A study of Sus scrofa with 16 samples.

How the data were processed

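Small RNA was sequenced from the endometrium, the lining of the uterus, of 15 sows on day 10 of pregnancy. From insemination the sows had been fed oestradiol-17β at 0.05, 10 or 1000 µg per kg body weight per day, or the ethanol carrier alone. Per the labels' protocols, RNA was extracted with TRIzol and the libraries were made with the NEBNext small RNA kit. Sow 7 of the 0.05 group was extracted 2 times, which gave 16 libraries. Per the labels, the libraries of the other sows come from separate animals. The 2 libraries of sow 7 were summed into 1 replicate, so that the groups hold 4 control sows, 3 sows at 0.05, 4 at 10 and 4 at 1000 µg/kg/day.

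The deposited files hold, for each library, every distinct read sequence and its raw count. The reads are 17 to 49 nt long and no adapter step is described in the sources used here. Per the submitters' processing notes, FastQC and the builds Sscrofa10.2, GRCh37.p5, UMD3.1 and GRCm38 were named, with no role given, and no aligner is named. The deposited counts carried no normalization. The total was 4497096 to 14945018 reads per library, of which 46.7 to 78.4% were 18 to 26 nt long. Reads carry no molecular identifiers, so floors drawn from counts cover counting error only. The 95% confidence intervals come from the edgeR fit described below and include the spread between sows.

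No reference sequence or miRNA annotation was used here. The plan fixed before the data were examined set counts per annotated miRNA, and for the case of no reference the group of 18 to 26 nt reads that share their first 18 nt. That group was the feature here, printed as its most abundant read. A name such as let-7 is a seed-family name: nucleotides 2 to 8 of the reads equal the seed of that family, the other bases were not checked, and a seed can belong to several families (miR-25, miR-92 and miR-367 share 1 seed). The planned share of reads assigned to miRNAs could not be formed without an annotation, and the share of reads in tested groups with a listed seed stands in its place. Identities given for other reads (tRNA, rRNA and snRNA) are background knowledge, not matches to a reference.

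Groups with at least 30 reads over all libraries were kept (26704), and 11108 passed edgeR's filterByExpr by group. These held 93.77% of all 18 to 26 nt reads. TMM factors ran from 0.732 to 1.26. The main test was edgeR's quasi-likelihood F-test with robust estimation (glmQLFit and glmQLFTest) over all 15 sows, with Benjamini-Hochberg adjustment and calls at an adjusted p under 0.05. The terms were each dose minus control, the 3 dose coefficients together, and dose rank. CPM values are relative to the TMM-scaled 18 to 26 nt total, and RPM values to all deposited reads. The biological coefficient of variation was 0.337. The 14 miRNA lists were fixed before the data were examined. A list is the set of tested groups with a seed of the list. The DLK1-DIO3 imprinted cluster list had no fixed seeds and was not tested, which left 13. Lists were tested with camera at a preset inter-gene correlation of 0.01 on log2 CPM with a prior count of 2, beside camera with an estimated correlation and fry. Lists overlap, and many members are 1-base variants of an abundant read, so members are not independent.

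The rule for named read groups was also fixed before the data were examined. It takes the called groups, the 10 smallest p-values of each dose where fewer are called, the 2 members of each list with the smallest p at 1000 µg/kg/day, up to 4 members of called lists, and the 10 most abundant groups. Added after the data were seen were the sum of all reads per seed (52 families with a mean of at least 10 reads), of which the 6 most abundant and those with an unadjusted p under 0.05 are given, the reads of 28 to 36 nt, and the U2 site. Measures of library composition were compared by two-sided exact permutation tests of group means over 35 splits, adjusted over 12 tests, with a smallest possible p of 0.0286. The 5 most abundant fragments of 28 to 36 nt were compared in the same way, adjusted over 15 tests, in RPM, and 1 of the 5 is not reported here. Libraries fell into 3 classes by length profile, a split set after the data were seen. Class A has under 8% of reads of 17 to 19 nt. Of the others, class B has under 5% of reads of 40 nt or more and class C has 5% or more.

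On simulated counts in which 100 groups changed 2-fold and 100 changed 4-fold, the test at 1000 µg/kg/day recovered 10% and 65%, with 6 false calls among 10030 tested groups. At 10 µg/kg/day it recovered 12% and 77%, with 5 false calls among 9718. At 0.05 µg/kg/day it recovered 9% and 62%, with 3 false calls among 9775. For the seed families at 1000 µg/kg/day, 5 of 10 changed 2-fold and 10 of 10 changed 4-fold were recovered among 52, with 0 false calls. The simulated groups varied independently and held no length classes. These rates therefore need not hold in the real libraries, which have such classes. Alternatives covered normalization, the DESeq2 test, low-count filters, the samples in the fit, the handling of sow 7, robust estimation, single sequences, the threshold, the dose scale, list tests and each sow left out. Added after the data were seen were library class as a covariate or held fixed, the merging of groups 1 base away from a group at least 20 times as abundant, and the tests on seed families and longer reads. All fits with library class as a covariate used extraction 7b alone for sow 7. Computation used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.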

Results

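Small RNA of the endometrium was profiled in sows on day 10 of pregnancy, after oral oestradiol-17β, the main oestrogen of the ovary, at 0.05, 10 or 1000 µg/kg/day from insemination. The design asks which endometrial miRNAs respond to each dose. The groups held 4 control sows, 3 sows at 0.05, 4 at 10 and 4 at 1000 µg/kg/day. Depth ran from 7363900 to 11084974 reads per sow in control, from 6198464 to 18525580 at 0.05, from 9285240 to 14945018 at 10 and from 4497096 to 14085579 at 1000 µg/kg/day.

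The endometrial libraries were led by reads of 22 nt, and the most abundant read group was TAGCTTATCAGACTGATGTTGAC with the miR-21 seed. It had 127520 ± 46506 CPM in control, 97569 ± 4580.5 at 0.05, 152270 ± 70983 at 10 and 103090 ± 19322 at 1000 µg/kg/day (SD, n = 4, 3, 4 and 4). TGAGATGAAGCACTGTAGCTCT with the miR-143 seed, a miRNA typical of smooth muscle and stroma, had 59736 ± 18832 CPM in control (SD, n = 4). 2 groups with the miR-10 seed, TACCCTGTAGAACCGAATTTGT and TACCCTGTAGATCCGAATTTGT, had 32225 ± 9082 and 20939 ± 3611 CPM in control. 2 let-7 groups, TGAGGTAGTAGTTTGTGCTGTT and TGAGGTAGTAGGTTGTATAGTT, had 30193 ± 8646 and 22325 ± 3782 CPM. TCAGTGCACTACAGAACTTTGT (seed of miR-148 and miR-152), TTCACAGTGGCTAAGTTCTGC (miR-27 seed) and TTCAAGTAATCCAGGATAGGCT (miR-26 seed) had 21600 ± 4865, 20529 ± 2762 and 17314 ± 4287 CPM in control. The remaining group among the 10 most abundant, CGCGACCTCAGATCAGAC, has the 5′ end of 28S rRNA and stood at 19652 ± 7889 CPM.

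**Figure D1:**
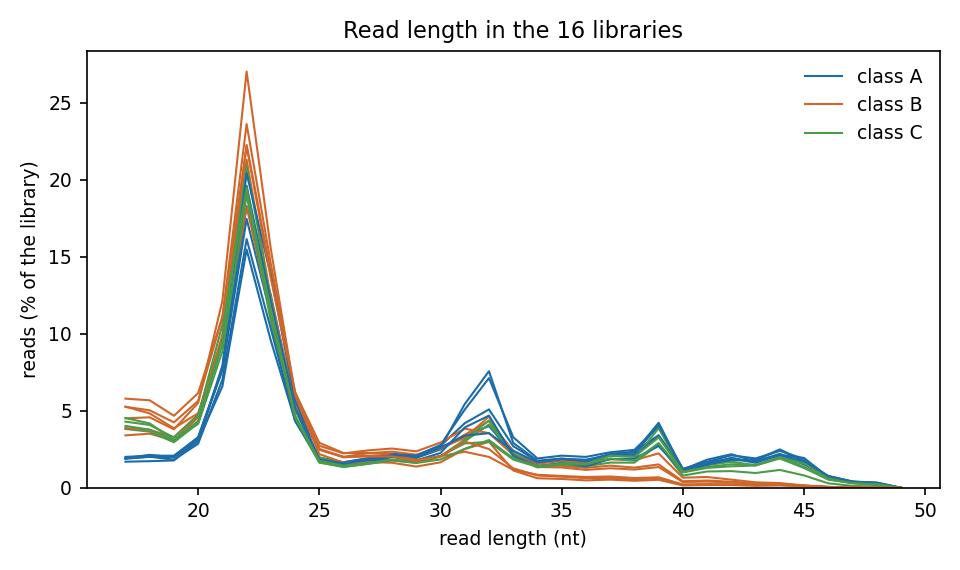
Read length in nt (x axis) against the percent of each library's reads (y axis), 1 line per library for all 16 libraries, coloured by length class. Reads of 40 nt or more made up 11.3 to 12.6% of class A, 0.976 to 2.83% of class B and 6.38 to 10.18% of class C libraries.

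The libraries differed in length profile within the dose groups. Class A held 6 libraries, with 5.20 to 6.17% of reads of 17 to 19 nt, class B held 6 with 9.99 to 16.1%, and class C held 4 with 10.4 to 11.8%. Control and 10 µg/kg/day had 2 libraries in class A and 2 in class B, whereas 0.05 and 1000 µg/kg/day had 1 in A, 1 in B and 2 in C. In a fit with dose and class, 905 of 11103 read groups differed between class B and class A (edgeR, adjusted p under 0.05; 371 higher and 534 lower in B), and 0 differed between class C and class A, with 1134 at an unadjusted p under 0.05.

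At 1000 µg/kg/day, the highest dose, no miRNA seed family and no read group passed the test against control. The miR-21 family stood at 105300 ± 19708 CPM against 130200 ± 47582 in control (SD, n = 4 and 4), a log2 difference of -0.31 (95% CI -0.92 to 0.31), which was -0.07 without control sow 2, -0.48 without control sow 4 and -0.19 when scaled by all deposited reads. The let-7 family, whose members restrain proliferation, stood at 105680 ± 22219 against 96171 ± 11979 CPM, with a log2 difference of 0.14 (95% CI -0.37 to 0.64), and -0.02 without sow 12. The miR-143 family had a log2 difference of 0.22 (95% CI -0.50 to 0.94), which was -0.38 with library class as a covariate and -0.34 without sow 13. The miR-30, miR-26 and miR-199-5p families lay at 0.11, 0.10 and -0.09 on the log2 scale, at -0.058, 0.0082 and -0.042 with library class as a covariate, and miR-199-5p at 0.03 when scaled by all deposited reads. Of the erythroid families, carried in red blood cells, miR-451 stood at 2525 ± 1384 against 1455 ± 167 CPM (log2 0.80, 95% CI 0.08 to 1.51) and miR-486 at 85.5 ± 30.003 against 48.2 ± 23.4 CPM (log2 0.82, 95% CI 0.03 to 1.61). Both had an adjusted p of 0.726 by edgeR. With library class as a covariate the log2 difference of miR-451 was 0.35 and that of miR-486 0.72. Sow 13 had 4194 CPM of miR-451 and sow 15 had 836, below all control sows, while the other 3 dosed sows lay above all of them. Its log2 difference was 0.44 without sow 13 and 1.09 without sow 15, where the adjusted p was 0.0519 by edgeR.

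0 of 52 seed families were called by edgeR at 1000 µg/kg/day, and for 29 of the 37 families with a mean of at least 100 CPM the 95% interval lay within 1 log2 unit of control on both sides. Of 11108 read groups 0 were called by edgeR, with 502 at an unadjusted p under 0.05 against 555 expected with no effect, and DESeq2 called 0, with 455. The fit of these 8 sows alone called 1 of 8593 read groups, which was higher than in control (adjusted p = 0.000414 by edgeR). That group did not pass in the fit of all sows. Fits within class A and within class B hold 1 high-dose library and 2 control libraries each and are given with the dependence on processing. The miR-122 family, typical of liver, stood at 31.0 ± 8.58 against 70.1 ± 85.1 CPM (log2 -1.18, 95% CI -2.24 to -0.12, adjusted p = 0.726), where control sow 2 had 198 CPM and the other control sows 26.1 to 28.7. Without sow 2 the log2 difference was 0.16. Its outlying reads, AGGAGTGTGTAACAACTCA, carry the miR-122 seed but their other bases were not checked, so they may not be miR-122.

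**Figure D2:**
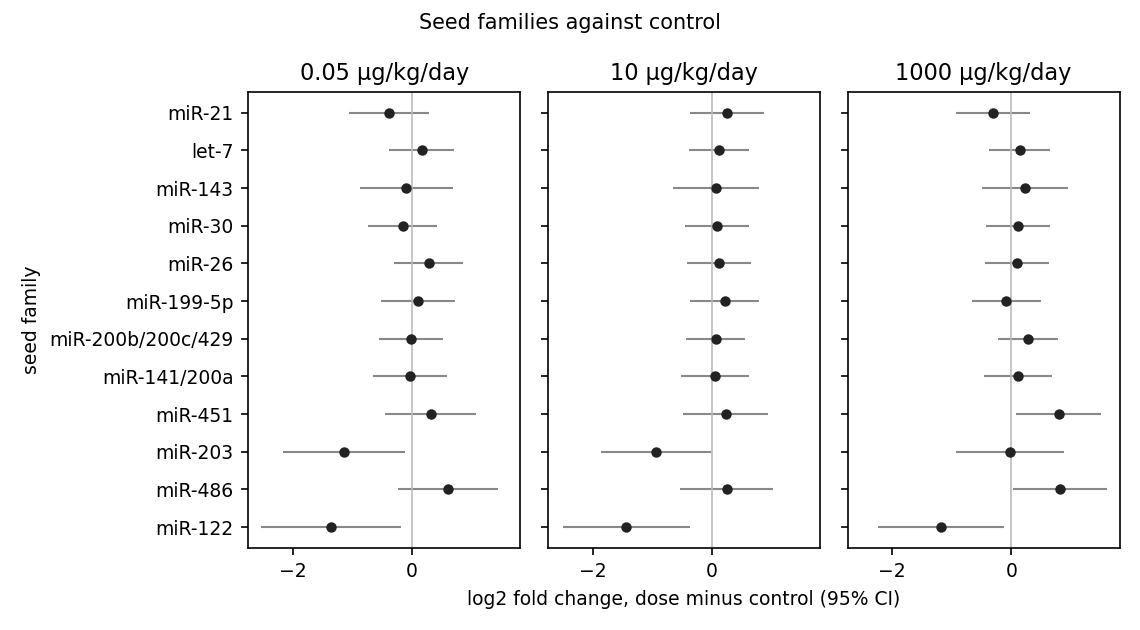
Log2 fold change of 12 miRNA seed families (rows, by abundance), each dose minus control (x axis, dimensionless), with points for edgeR estimates and bars for 95% confidence intervals, over 4 control sows and 3, 4 and 4 dosed sows. 0 of 52 families passed the adjusted threshold at any of the 3 doses, and miR-122 rests on control sow 2.

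5 of 13 miRNA lists were called at 1000 µg/kg/day by camera with the preset correlation, all shifted upwards relative to other groups, and 0 with an estimated correlation or by fry. In the epithelial miR-200 list, 57 of 64 groups were higher than in control (median log2 0.30, adjusted p = 9.12e-10), and the adjusted p was 0.696 with an estimated correlation. In the erythroid list, 16 of 18 were higher (median log2 0.73, adjusted p = 9.13e-06), and in the epithelial list outside miR-200 39 of 60 (median log2 0.16, adjusted p = 9.13e-06), each with an adjusted p of 0.696 with an estimated correlation. In the let-7 list 105 of 135 were higher (median log2 0.20, adjusted p = 4.71e-07), with an adjusted p of 0.758 with an estimated correlation. In the implantation-linked list 141 of 235 were higher (median log2 0.11, adjusted p = 0.00767), with an adjusted p of 0.889 with an estimated correlation, while the summed level was 192758 against 212604 CPM. In each of these 5 lists 0 groups were called, also when adjusted over the list alone. The count of called lists was 2 with library class as a covariate, 1 after merging 1-base variants, 2 among groups of at least 10 CPM, 10 without control sow 1, 9 without sow 15 and 3 without sow 13.

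The other 8 lists were not called at 1000 µg/kg/day. Stromal and smooth muscle groups had a median log2 of 0.08 (63 of 112 higher), oestrogen-linked groups -0.02 (63 of 134), miR-17-92 groups -0.09 (22 of 55) and pluripotent embryo groups 0.04 (17 of 33). Of these 33, 29 carry the seed that miR-367 shares with miR-25 and miR-92, and they also belong to the miR-17-92 list. The markers of other tissues had medians of 0.13 (endothelial, 11 of 15 higher), -0.11 (leukocyte, 3 of 14), 0.41 (skeletal and cardiac muscle, 9 of 11) and -0.10 (liver and brain, 7 of 16). 0 members of these lists were called, also when adjusted over the list alone.

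Among the members with the smallest p of each list at 1000 µg/kg/day, AGGCAGTGTATTGTTAGCTGGC (seed of miR-34 and miR-449, families of ciliated epithelium) stood at 27.7 ± 7.22 against 13.4 ± 5.61 CPM (log2 1.05, 95% CI 0.29 to 1.80; SD, n = 4 and 4). TGAGAACTGAATTCCATAGGCTG (miR-146 seed, a family of inflammatory signalling) stood at 236 ± 75.8 against 436 ± 231 CPM (log2 -0.89, 95% CI -1.66 to -0.12). AGAGGTAGTAGGTTGCATAGTT (let-7 seed) stood at 851 ± 241 against 585.45 ± 139 CPM (log2 0.54, 95% CI 0.04 to 1.04), and the main read of miR-451, AAACCGTTACCATTACTGAGT, at 2442 ± 1353 against 1398 ± 161 CPM. Of the 24 read groups this part of the rule names, 14 lie 1 base from a group at least 20 times as abundant, such as TGTAAACATCCTCGACTTGAAGCT (miR-30 seed) at 5.398 ± 1.59 against 2.54 ± 0.743 CPM beside TGTAAACATCCTCGACTGGAAGCT at 18539 against 16676 CPM. None of the 24 passed adjustment over all groups.

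Of the 10 read groups with the smallest p at 1000 µg/kg/day, none of which passed, 8 were lower and 2 higher than in control. ATCGTATAGTGGTTAGTACTCTGC, with the sequence of the 5′ part of tRNA-His, stood at 38.1 ± 8.87 against 82.5 ± 33.8 CPM (log2 -1.11, 95% CI -1.72 to -0.50). 4 were 1-base variants of TGACGAATTTAACGCCGATCTGACC or its form with 1 base more at the 5′ end, whose identity was not established, and the former stood at 3645 against 5974 CPM in control (log2 -0.71). CATGAGAGGTGTAGAATAAGTGGGAG, a 28S rRNA fragment, stood at 19.2 ± 4.01 against 38.8 ± 13.4 CPM (log2 -1.01, 95% CI -1.59 to -0.43).

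At 10 µg/kg/day the abundant miRNA families again did not separate from control. The miR-21 family stood at 155560 ± 72651 CPM and the let-7 family at 104860 ± 27022 CPM (SD, n = 4), against 130200 ± 47582 and 96171 ± 11979 in control (SD, n = 4). The miR-203 family, typical of squamous epithelium, stood at 654 ± 239 against 1255 ± 910 CPM (log2 -0.94, 95% CI -1.86 to -0.02, adjusted p = 0.974 by edgeR). Its control level rested on sows 2 and 4 with 2129 and 1952 CPM, beside 522 and 418 in sows 1 and 3, and without sow 2 the log2 difference was -0.56. The miR-122 family stood at 25.98 ± 5.19 against 70.1 ± 85.1 CPM (log2 -1.43, adjusted p = 0.536), and at a log2 of -0.089 without control sow 2. 0 of 52 families were called, and 32 of the 37 of at least 100 CPM had an interval within 1 log2 unit. 0 of 11108 read groups were called by edgeR, with 374 at an unadjusted p under 0.05, and 0 by DESeq2, with 321. The count was 1 without control sow 2, sow 8 or sow 9, 1 within class A and 21 within class B, each with 2 libraries at this dose and 2 control libraries.

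4 lists were called at 10 µg/kg/day with the preset correlation, all shifted upwards, and 0 with an estimated correlation or by fry. 84 of 112 stromal and smooth muscle groups were higher (median log2 0.18, adjusted p = 0.000157), as were 181 of 235 implantation-linked groups (median log2 0.19, adjusted p = 0.000157), 102 of 135 let-7 groups (median log2 0.10, adjusted p = 0.00326) and 98 of 134 oestrogen-linked groups (median log2 0.12, adjusted p = 0.00326). Each had an adjusted p of 0.729 with an estimated correlation. 0 members of the 4 lists were called, also when adjusted over the list alone. 1 member of the skeletal and cardiac muscle list passed when adjusted over the list alone (adjusted p = 0.0205), TGGAATGTTTAGGACCACTAGT at 2.12 ± 0.767 against 6.38 ± 3.79 CPM, 1 base away from the far more abundant TGAAATGTTTAGGACCACTAGT at 582 against 1579 CPM. That base lies in the seed, so the abundant read does not share the seed that places the variant in the muscle list. Instead, the abundant read begins with the bases of the miR-203 seed, 1 position earlier than in a miR-203 family read. The control level of the variant rested on sows 2 and 4 with 10.8 and 8.23 CPM, beside 3.06 and 3.39 in sows 1 and 3. The miR-203 family was high in the same 2 control sows. The pass is therefore not evidence of a change in a muscle miRNA. The count of called lists was 0 after merging 1-base variants, 0 without control sow 4, 1 without sow 9, 8 without control sow 1, 10 without control sow 2 and 9 without sow 11. It was 7 when scaled by all deposited reads and 8 when groups with at least 1 read in every sow were tested.

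The smallest p at 10 µg/kg/day belonged to TCTCTATCCGAGGACAATATATT, which has the sequence of U2 snRNA, a component of the spliceosome. It had 3.34 ± 2.25 CPM (SD, n = 4) and 119 reads, against 0 reads in the control sows, at least 26.4-fold higher over a floor of 3 reads in the group, with an adjusted p of 0.477. Sow 9 of this dose had 0 reads. Of the 10 smallest p-values 4 were higher and 6 lower than in control, and none passed. TCCGTTTGCCTGTTTTGCTGA stood at 7.53 ± 1.33 against 3.50 ± 1.16 CPM and CCCGCGGGCGCTCTCCAGCCCTTT at 5.43 ± 4.197 against 14.2 ± 3.12 CPM. The 28S rRNA fragments CGTGGAGCCGGGCGTGGAATGCGAGT, CGGCCCTGGCGGAGCGCTGAGA and CAGCCGACTTAGAACTGGTGCGGACC stood at 1.59 ± 0.432, 9.69 ± 0.917 and 5.50 ± 0.885 CPM against 7.13 ± 6.95, 24.3 ± 18.9 and 14.6 ± 12.96 in control, where sow 2 had the highest level of each.

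At 0.05 µg/kg/day, the lowest dose, the miR-203 family stood at 568 ± 127 CPM (SD, n = 3) against 1255 ± 910 in control (SD, n = 4), a log2 difference of -1.14 (95% CI -2.16 to -0.13, adjusted p = 0.755 by edgeR), again with control sows 2 and 4 far above the other control sows. The miR-122 family stood at 27.1 ± 3.24 CPM (log2 -1.37, adjusted p = 0.755, and -0.027 without control sow 2), the miR-21 family at 99591 ± 4713 CPM and the let-7 family at 107480 ± 5198 CPM. 0 of 52 families were called and 23 of the 37 of at least 100 CPM had an interval within 1 log2 unit. 0 of 11108 read groups were called by edgeR, with 263 at an unadjusted p under 0.05, and 0 by DESeq2, with 244. The count was 3 within class A and 8 within class B, each with 1 library at this dose and 2 control libraries.

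2 lists were called at 0.05 µg/kg/day with the preset correlation and 0 with an estimated correlation or by fry. 98 of 135 let-7 groups were higher (median log2 0.19, adjusted p = 3.55e-06) and 49 of 60 epithelial groups outside miR-200 were lower (median log2 -0.46, adjusted p = 0.00349), each with an adjusted p of 0.944 with an estimated correlation. 0 members of either list were called, also when adjusted over the list alone. 1 skeletal and cardiac muscle member passed over its list alone, TGGAATGTTTAGGACCACTAGT at 1.71 ± 1.01 CPM (adjusted p = 0.0238 by edgeR), against the same uneven control level. It lies 1 base from TGAAATGTTTAGGACCACTAGT, which had 438 against 1579 CPM and does not share its seed. That abundant read begins with the bases of the miR-203 seed, so this pass too is not evidence of a change in a muscle miRNA. The count of called lists was 8 with library class as a covariate, 0 after merging 1-base variants, 5 when scaled by all deposited reads, 1 among groups of at least 10 CPM, 7, 6 and 4 without control sows 1, 2 and 4, 1 without sow 5 and 6 without sow 6. Of the 10 read groups with the smallest p, 4 were higher and 6 lower, and none passed. ATCGATGTGGTGATGTGGCGCT stood at 265 ± 24.2 against 163 ± 8.89 CPM (log2 0.70, 95% CI 0.26 to 1.14), and the 28S rRNA fragment AAGATGGTGAACTATGCCTGGGCA at 9.47 ± 4.44 against 23.3 ± 14.95 CPM.

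Across the doses, 0 of 11108 read groups were called by the edgeR test of the 3 coefficients together, with 337 at an unadjusted p under 0.05 and 0 called by DESeq2, with 348. At an adjusted p under 0.10, 1 group was called. For the trend over dose rank 0 were called by edgeR, with 436 at an unadjusted p under 0.05, and 0 by DESeq2, with 409. The 3-coefficient test called 3 groups within class A and 21 within class B, and 1 without sow 9, and the trend called 1 within class B.

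Library composition did not separate the doses from control. Reads of 20 to 24 nt made up 49.1 ± 5.42% in control, 46.5 ± 6.90% at 0.05, 54.2 ± 10.98% at 10 and 51.9 ± 6.21% at 1000 µg/kg/day (SD, n = 4, 3, 4 and 4). Reads in groups with a listed miRNA seed made up 25.9 ± 2.66%, 24.5 ± 2.999%, 28.8 ± 5.37% and 27.8 ± 1.64% of all reads in the same order. The 10 most abundant groups held 35.1 ± 3.87%, 34.4 ± 1.08%, 37.1 ± 5.07% and 35.5 ± 3.02% of 18 to 26 nt reads, and 3600 ± 156, 3553 ± 104, 3353 ± 385 and 3442 ± 168 groups were found at 10 CPM or more. The smallest of the 12 exact permutation p-values was 0.257 (two-sided; adjusted p = 0.762).

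The 2 extractions of sow 7 gave a Pearson r of 0.939 across 3644 read groups of at least 10 CPM, which are not independent replicates, and a median absolute log2 difference of 0.265. In 23 pairs of libraries from different sows of the same dose the median r was 0.936 (range 0.876 to 0.956) and the median difference 0.349 (range 0.258 to 0.717). The extractions fell into classes B and C.

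Reads of 28 to 36 nt, examined after the data were seen, were led by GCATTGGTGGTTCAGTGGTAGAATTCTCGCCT, a 32-nt fragment with the sequence of the 5′ part of tRNA-Gly. It stood at 16333 ± 3172 RPM at 1000 µg/kg/day against 30246 ± 6025 in control (SD, n = 4 and 4; ratio 0.540), and all 4 dosed sows lay below all 4 control sows. The exact permutation p was 0.0286 (two-sided), the smallest that 4 against 4 can give, and the adjusted p over 15 tests was 0.343. At 0.05 and 10 µg/kg/day it stood at 38282 ± 19549 (SD, n = 3) and 36664 ± 26660 (SD, n = 4). Relative to other reads of this length the log2 difference at 1000 µg/kg/day was -0.65 (adjusted p = 0.9996 by edgeR), and -0.36 with library class as a covariate. On that scale the separation was lost, with sow 15 at 148010 CPM above control sows 2 and 4 at 135710 and 132500. Within class A the high-dose library had 17323 RPM and the 2 control libraries a mean of 32640. Within class B these were 20196 and 27852, and class C held no control. In class B the library at 0.05 µg/kg/day (18168 RPM) and the mean of those at 10 (17594) were lower still. In class A both were above the control mean (60696 and 55734). The 30-nt end of 5S rRNA, CCGCCTGGGAATACCGGGTGCTGTAGGCTT, stood at 7429 ± 2787 against 10380 ± 1248 RPM (ratio 0.716, exact permutation p = 0.143). Its 32-nt form, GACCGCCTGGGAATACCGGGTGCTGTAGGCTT, stood at 5640 ± 2395 against 8294 ± 1195 RPM (ratio 0.680, exact permutation p = 0.114), whereas the 36-nt 28S rRNA fragment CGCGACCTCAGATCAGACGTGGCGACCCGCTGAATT was level (6379 ± 1450 against 6377 ± 1226 RPM, ratio 1.00).

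**Figure D3:**
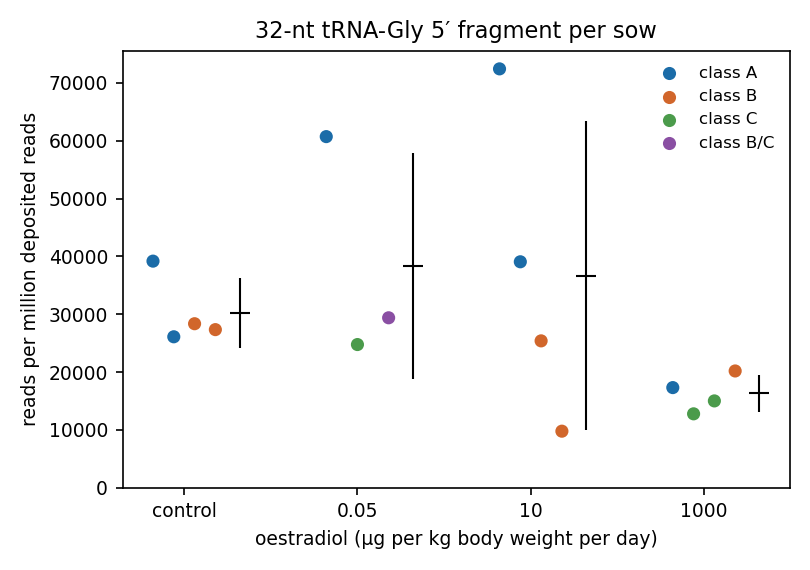
Reads of the 32-nt tRNA-Gly 5′ fragment in RPM of all deposited reads (y axis) by oestradiol dose (x axis), 1 point per sow coloured by length class, with the mean and SD of each group beside the points. The 4 sows at 1000 µg/kg/day lie between 12790 and 20196, below the 4 control sows at 26104 to 39176.

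Over all 28 to 36 nt read groups, 0 of 7287 were called by edgeR at any single dose, with 147, 245 and 252 at an unadjusted p under 0.05 at 0.05, 10 and 1000 µg/kg/day. At 10 µg/kg/day the count was 1 with library class as a covariate and 3 without sow 9. The test of the 3 coefficients together called 1, TCAGTTTAATATCTGATACGTTCTCTATC, another stretch of U2 snRNA (adjusted p = 0.0214), with a log2 difference of 2.76 at 10 µg/kg/day. The call rests on the full set of sows: the count was 0 when any of 13 of the 15 sows was left out, 1 without sow 5 and 3 without sow 9. Where the count was 0, this group still had the smallest adjusted p (0.0502 to 0.0797 by edgeR), except without sow 8, 10 or 11. The printed reads of both U2 groups carry C8T, a substitution in the U2 stretch GATACGTCCTCTATC. Positions are counted from 1 at the 5′ end of its 15 bases. The first 18 nt that define the 29-nt group end before this base. That group can therefore hold both versions of the site, and its log2 difference is not a measure of the C8T version alone. The C8T version made up 7.36, 9.04 and 11.6% of the site's reads in sows 8, 10 and 11 at 10 µg/kg/day, and 0.194% in sow 9. In control it was 0.105 to 0.203%, at 0.05 µg/kg/day 0.0618 to 0.401% and at 1000 µg/kg/day 0 to 0.204%. The share at 10 µg/kg/day against control had an exact permutation p of 0.0571 (two-sided, n = 4 and 4).

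**Figure D4:**
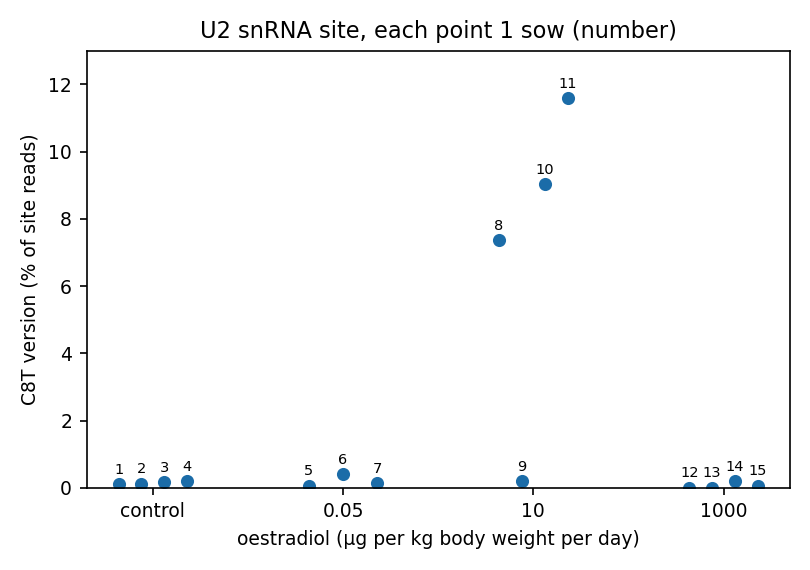
Percent of reads over the U2 snRNA site that carry the C8T version (y axis) by oestradiol dose (x axis), 1 point per sow, labelled with the sow's number. Sows 8, 10 and 11 lie at 7.36, 9.04 and 11.6%, and the other 12 sows at 0.401% or less.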

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

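The comparison of single sows with the rest of their group was set before the data were examined, and the tests on U2 snRNA were chosen after the U2 read groups had been seen. Within control, 10 µg/kg/day and 1000 µg/kg/day, 239 sets of 4 sows were screened for 1 sow far from the other 3, and 20 were flagged, where chance flags about 1 in 20, or 12 (11.95). The 3 sows at 0.05 µg/kg/day are too few for the screen.

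Control sow 2 stood apart in 6 of them. Its miR-122 seed family was at 198 CPM beside 26.1 to 28.7 in the other control sows, and the read group AGGAGTGTGTAACAACTCA, which carries that seed, at 177 CPM beside 4.45 to 10.1. The 28S rRNA fragment CAGCCGACTTAGAACTGGTGCGGACC was at 33.8 CPM beside 6.62 to 11.2, TAGTGGTTAGTACTCTGT at 6.70 CPM beside 4.02 to 4.33, and AGACGAATTTAACGCCGATCTGACC at 20.6 CPM beside 31.1 to 32.6. ACAACGGGAACTCCATATTTTT was at 0.516 CPM in sow 2 and had 0 reads in the other control sows. Control sow 1 had 44224 CPM of the miR-30 seed family beside 35305 to 36453, and 101 CPM of the 28S fragment ATGAGAGGTGTAGAATAAGTGGGAG beside 40.5 to 45.7.

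At 10 µg/kg/day, sow 8 had 53.9 CPM of ATGAGAGGTGTAGAATAAGTGGGAG beside 28.4 to 32.3. Sow 9 had 11.5 CPM of TAATACTGCCTAGTAATGATGACT (miR-200 seed) beside 4.56 to 5.27. Sow 11 had 2.72 CPM of TCACAGTGAACTGGTCTCTTT beside 2.11 to 2.20 and 7.19 CPM of TGACGAATTTAACGCTGATCTGACC beside 6.11 to 6.14.

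At 1000 µg/kg/day, sow 12 had 38.5 CPM of AGGCAGTGTATTGTTAGCTGGC (seed of miR-34 and miR-449) beside 23.9 to 24.3, 51.2 CPM of ATCGTATAGTGGTTAGTACTCTGC (5′ part of tRNA-His) beside 32.7 to 35.6 and 2.22 CPM of GGGTCGCGCCGTCGGGCCCGGGG beside 1.23 to 1.31. Sow 13 had 10.0 CPM of TGGAATGTAGAGAAGTATGTAT (10.048; seed of miR-1 and miR-206) beside 0.697 to 1.53, 7.54 CPM of AGGAGTGTGTAACAACTCA beside 4.43 to 4.79 and 4.61 CPM of AAAGGCACGAGAGGACAATT (miR-124 seed) beside 2.09 to 2.49. Sow 15 had 0.0871 CPM of the U2 group TCTCTATCCGAGGACAATATATT, a single read, and the other sows of this dose 0.

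The U2 snRNA groups were flagged on 2 grounds. Sow 9 had 0 CPM of TCTCTATCCGAGGACAATATATT beside 4.12 to 4.82 in the other sows at 10 µg/kg/day, and the 29-nt group TCAGTTTAATATCTGATACGTTCTCTATC, in reads outside the planned 18 to 26 nt, had a mean of 14.8 CPM at that dose against 2.15 in control. An effect of the dose of like size in every sow is argued against by sow 9, whose share of the C8T version was 0.194%, within the control range that ends at 0.203%. However, its 3.98 CPM of the 29-nt group lay above the control sows (1.75 to 2.82) and the highest sow of the other doses (3.06). That group can hold both versions of the site, so its level is not a measure of the C8T version. A sequence variant carried by sows 8, 10 and 11 stays open as a candidate. Both versions together were at 187 ± 98.6 RPM against 231 ± 79.5 in control (ratio 0.811, exact permutation p = 0.486, SD, n = 4 and 4). For the C8T share the exact permutation p was 0.0571. The C8T version made up at most 11.6% of the site's reads. The total therefore cannot tell such a variant from a rise of that version alone. It was also not level, at 94.0 and 122 RPM in sows 10 and 11 beside 156 to 342 in control. The genomes of the sows were not analysed here, and kinship between them and an effect of dose confined to some sows stay open, as neither was tested.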

How the results depend on the processing

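The absence of called read groups at each dose held under every scaling, low-count filter, handling of sow 7, robust option, single-sequence feature, under DESeq2, and when adjusted over the 755 groups with a listed seed. Adjusted over the skeletal and cardiac muscle list alone, 1 member passed at 0.05 and 1 at 10 µg/kg/day. Both times it was the same variant, 1 base from an abundant read that begins with the bases of the miR-203 seed. Neither pass is evidence of a change in a muscle miRNA. Counts rose from 0 in fits restricted by class: within class A to 3 at 0.05, 1 at 10, 1 at 1000 µg/kg/day and 3 over the 3 coefficients, and within class B to 8, 21, 11 and 21, with 1 for the trend. These fits hold 6 libraries each, with 1 library at 0.05 and 1 at 1000, which is assumed to vary like the other groups. The fit of the 2 groups compared called 1 at 1000, higher than in control (adjusted p = 0.000414 by edgeR). An adjusted p under 0.10 gave 1 over the 3 coefficients. With 1 sow left out the counts ran from 0 to 1 at 10 and from 0 to 1 over the 3 coefficients. For reads of 28 to 36 nt the count at 10 was 1 with class as a covariate and 0 to 3 with 1 sow left out, and the count over the 3 coefficients 0 to 3, being 0 without any of 13 of the 15 sows. Unless stated, the cause was not tested.

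Called lists did not hold. At 0.05 µg/kg/day (2 lists) the count was 0 with an estimated correlation, 0 by fry, 5 scaled by all deposited reads, 1 at 10 CPM or more, 8 with class as a covariate, 0 with 1-base variants merged and 1 to 7 with 1 sow left out. At 10 (4 lists) it was 0 with an estimated correlation, 0 by fry, 7 scaled by all deposited reads, 8 with at least 1 read in every sow as the only filter, 0 merged and 0 to 10 with 1 sow left out. At 1000 (5 lists) it was 0 with an estimated correlation, 0 by fry, 2 at 10 CPM or more, 2 with class, 1 merged and 3 to 10 with 1 sow left out. 5 of 11 list results turned in direction when 1 sow was left out. At 10 their adjusted p then ran from 2.66e-13 to 0.932 (implantation-linked), 1.11e-09 to 0.932 (let-7), 5.76e-10 to 0.932 (oestrogen-linked) and 1.63e-10 to 0.932 (stromal), and at 1000 from 3.80e-06 to 0.739 (implantation-linked).

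Of 54 named results 8 turned in direction, all at 1000 µg/kg/day and none called. In log2, within class B TCGTACCGTGAGTAACAATGCG was at -0.26, TCGTACCGTGAGTAATGATGCG at -0.22, TCCTGTACTGAGCTGCCCCGAGT at -0.21, AAACCGTTACCATTACTGAGT at -0.76, AAAGGCACGAGAGGACAATT at -0.16 and TGGAATGTAGAGAAGTATGTAT at -0.40. Within class A TGAGAACTGAATTCCGTAGGCT was at 0.68, ATAAGACGAGAAGACCCTATGGAGCT at -0.057 and TGGAATGTAGAGAAGTATGTAT at -1.27. With class as a covariate TCGTACCGTGAGTAATGATGCG was at -0.094 and TGGAATGTAGAGAAGTATGTAT at -0.12, the latter at -0.61 to 1.41 with 1 sow left out.

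Of 14 seed-family results 7 turned, all at 1000 µg/kg/day. With class as a covariate miR-143 was at -0.38, miR-30 at -0.058 and miR-203 at 0.14; scaled by all deposited reads miR-199-5p was at 0.032 and miR-203 at 0.079. miR-203 was at 0.0082 with DESeq2 size factors, 0.0053 at 10 CPM or more and 0.0090 merged. With 1 sow left out miR-199-5p ran from -0.29 to 0.067, miR-143 from -0.34 to 0.44, let-7 from -0.019 to 0.23, miR-122 from -1.51 to 0.16, miR-26 from -0.040 to 0.25 and miR-203 from -0.28 to 0.36.

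For composition, the share of the top 5 groups was lower than control by 0.509 points at 1000 (-0.509), and with extraction 7a only the groups found at 0.05 were 11.4 more than in control. With 1 sow left out the difference from control in reads of 20 to 24 nt ran from -5.70 to 1.10 points at 0.05 and -0.265 to 5.31 at 1000, in listed seeds from -2.37 to 0.312 at 0.05, in the 10 most abundant groups from -2.19 to 0.956 at 0.05 and -1.07 to 2.07 at 1000, and in groups found from -110 to 17.7 at 0.05.

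For the fragments at 10 µg/kg/day, in RPM of the reads of 28 to 36 nt the 5S difference was 3589; at 1000, in RPM of the reads of 18 to 26 nt, the 28S fragment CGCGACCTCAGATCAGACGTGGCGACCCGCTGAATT was at -329. With 1 sow left out tRNA-Gly ran from -3171 to 14796 at 0.05 and -5495 to 15377 at 10, and the 28S fragment from -556 to 534 at 1000. The lower tRNA-Gly level at 1000 kept its direction throughout.

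The class fits, the merging and all tests on seed families and fragments were chosen after the data were seen. 2 choices set before the data were seen were not run as such: reads that fit several miRNAs, as the groups do not overlap, and groups by the first 18 nt, which became the main feature. In place of a run with no filter, groups needed at least 1 read in every sow (14807 tested). No paired analysis was possible because the numbers mark separate sows and the groups share none. With 3 or 4 sows per group and 4497096 to 18525580 reads per sow, groups of few reads are limited by depth, and 2-fold changes were mostly missed in the simulation.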

Other observations

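All tests on library class and on the tRNA-Gly fragment were chosen after the results were seen, as were the counts of splits for read groups, seed families and single doses of the longer reads; the counts of splits for lists and for the longer reads over all doses were set before.

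The 3 classes of length profile are a pattern of the libraries. A property of the sow cannot be told apart from library preparation, since only sow 7 was extracted 2 times: its extractions fell into classes B and C and differed by 4.27 percentage points in the share of reads of 40 nt or more, beside a smallest gap of 6.58 between class B and class C libraries of the other sows. Dose alone does not set the class, since classes A and B hold all 4 groups. The smallest exact permutation p of the share between a dose and control was 0.629, but with 3 or 4 sows per group this cannot exclude an effect of dose. A difference in size selection or library preparation stays open as a candidate explanation, since the labels give no batch. Libraries of class C come only from 0.05 and 1000 µg/kg/day, so class C and those doses are partly confounded.

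In RPM of all deposited reads, the 32-nt tRNA-Gly 5′ fragment was lower in all 4 sows at 1000 µg/kg/day than in all control sows, with a log2 ratio of geometric means of -0.89. Relative to reads of 28 to 36 nt this separation was lost, as sow 15 lay above control sows 2 and 4. On that scale the log2 difference was -0.65, or -0.36 with class as a covariate. Library class cannot be told apart from dose: within classes A and B both high-dose libraries lay below their controls, but the stratified exact permutation p was 0.111, the smallest these libraries can give, and class C has no control. A loss of reads of about this length cannot be told apart either, as the 30-nt 5S fragment was lower without passing a test and the log2 ratio of the tRNA-Gly fragment to it was 1.21 ± 0.395 against 1.53 ± 0.380 in control (exact permutation p = 0.286, SD, n = 4 and 4). The error of extraction and library preparation stays open, since only sow 7 was extracted 2 times (0.998 apart on the log2 scale). An effect of oestradiol stays open as a hypothesis that these libraries do not decide.

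Chance cannot be excluded for the called lists. At 1000 µg/kg/day 24 of the 35 splits of the 8 sows gave at least the 5 lists of the real split, and the highest of the others gave 12. At 10 µg/kg/day 29 of 35 gave at least 4 (highest other 11), and at 0.05 µg/kg/day 31 of 35 gave at least 2 (highest other 10). The preset correlation of 0.01 stands against estimated ones such as 0.506 for the miR-200 list and 0.407 for let-7, which may account for so many calls in arbitrary splits; with estimated correlations 0 lists were called at each dose.

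For read groups the real splits gave 0 calls, so that 35 of 35 splits at each dose and 100 of 100 drawn for the 3-coefficient test and for the trend gave as many. With 0 real calls this outcome was fixed in advance and does not test chance. The highest other split gave 0 at 1000, 261 at 10, 79 at 0.05, 5 over the 3 coefficients and 5 for the trend. The split with 261 put sows 3, 4, 10 and 11 on 1 side, which are the class B sows of control and 10 µg/kg/day, and the split with 79 put sows 3, 4 and 7 together, of which 3 and 4 are class B and 7 has a library in B and 1 in C. These splits point to the length classes as a structure of the samples. With class as a covariate, and extraction 7b alone for sow 7, 0 groups were called at each dose. Groups at an unadjusted p under 0.05 by edgeR were then 652 at 0.05, 468 at 10 and 518 at 1000 µg/kg/day, where 555 are expected with no effect. With extraction 7b alone and no class term these were 361, 361 and 497. For seed families 35 of 35 splits gave at least the real 0 at each dose, which was likewise fixed in advance, and the highest others gave 3 at 1000, 1 at 10 and 2 at 0.05.

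For the reads of 28 to 36 nt, 9 of 100 drawn splits gave at least the 1 call of the 3-coefficient test, with 40 as the highest other, so chance cannot be excluded. At single doses 35 of 35 splits gave at least the real 0, which was fixed in advance and does not test chance. The highest other was 1 at 1000, 397 at 10 and 2 at 0.05, and the split with 397 was again that of the class B sows 3, 4, 10 and 11.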
